A study of Mus musculus with 6 samples.

How the data were processed

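Total RNA of cultured neural stem cells from the subventricular zone of young (2 months) and aged (15 to 18 months) C57BL/6 mice was extracted, and 1 ug per library was depleted of rRNA and made into libraries with an MGI kit, per the labels' protocols. Each of the 6 libraries (3 per group) has its own table. The values are FPKM deposited by the authors with 2 decimals, 1 value per gene, per the file headers. TopHat, Cuffdiff and the mouse build mm10 are named in the submitters' processing notes, with no version, role or order. The sources used here do not give the annotation, strand setting, fragment filters or the normalization between libraries.

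Genes were matched by their Entrez identifier to a RefSeq table of GRCm38.p6 (the mm10 assembly), which held 16962 of the 17006 identifiers and gave the coordinates, counted from 1. In 32 cases a symbol that was blank or turned into a date was replaced from that table. Because FPKM are not counts, no count test was used. Low values came in steps that show what 1 read is worth, and these steps put the libraries at 5233000 to 5431000 counted reads. Of values between 0.3 and 3.5 estimated reads, 75.7% lay within 0.15 of a whole number, against 30.0% by chance. That share is partly built in, because the step was set on values near 1 read. Between 3.5 and 10.5 estimated reads, which did not set the step, the share was 49.5%, also against 30.0%. Estimated reads use transcript lengths and are approximate for genes with several transcripts and for very short RNAs. They served to judge depth and to set differences between libraries against read sampling. Intervals built on them resample genes and do not cover other sources of error.

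Samples were grouped by the age in their labels. The main test was limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend, all 6 libraries, no covariates) on log2(FPKM + 1), for the 11912 genes with a mean of at least 1 FPKM, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Log2 changes are on the scale of FPKM + 1, which understates the change of low genes. The test, 29 gene lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule took the 12 called genes with the largest log2 change in each direction whose groups did not overlap (without small RNA, clone-type and pseudogene symbols), up to 4 members with the smallest adjusted p of each list that passed or held 3 called genes, 10 fixed genes and the sex-linked genes. Of the genes it took, 2 are not reported here. Lists with at least 5 kept members were tested with camera (preset correlation 0.01, two-sided, adjusted over 23 lists), and again with an estimated correlation and with fry. The 5 lists of other cell types with fewer kept members and the sex-linked genes are described by value.

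On simulated values for 11747 genes, the test recovered 16.4% of genes changed 1.2-fold, 69.2% of those changed 1.5-fold and 80% of those changed 2-fold. Of its calls, 3.6% were false. The simulation had the depth of these libraries and a variance of 1.4 times that of read sampling for every gene. Among genes of many reads, the libraries of a group differed by more than that, so these shares may be too favourable there. Raising the glycolysis list 1.2-fold led camera to call that list and 0 of the 22 others. Genes were simulated independently, so that check could not show false list calls that come from correlated genes. Tables were prepared and figures drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. Alternatives covered the pseudocount (0.1 and 5), the filter (none, or a mean of 5 FPKM), 3 other scalings, limma's trend, robust and weighting options, a replicate block, leaving out small RNA symbols or each library in turn, and stricter thresholds. A filter on 20 estimated reads and removal of GC and length trends were added after the data had been seen. The alternatives meant for counts were not run, because the values are FPKM.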

Results

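The transcriptome was measured by bulk RNA sequencing in primary neural stem cells grown from the subventricular zone, the germinal layer along the lateral ventricles of the adult mouse brain. Cells came from C57BL/6 mice that were young (2 months) or aged (15 to 18 months), with 3 libraries per group. Tissue of 5 mice was pooled for dissociation and the cells were kept in proliferation medium before RNA was taken, so the libraries describe cultured cells and not the tissue. Each library has an FPKM value (fragments per kilobase of transcript, scaled to the size of the library) for 17006 genes, of which 15116 to 15238 were above 0 in a library. Read steps in the values put the depth at about 5233000 to 5431000 counted reads per library. The most abundant transcripts included Fabp7 (mean 2741 FPKM over the 6 libraries), Vim (1596 FPKM) and Olig1 (1440 FPKM), which are expressed by neural progenitors and glia.

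The design holds a single comparison, aged against young, which asks how the transcriptome of stem cells in culture differs with the age of the donor mice. Of 19 glycolysis genes, among them glucose and lactate carriers, 10 rose in aged libraries and 9 did not pass (list adjusted p = 0.132 with an estimated correlation). The angiogenic growth factor Vegfa rose too, while Igf2bp2, Twist1, Ndn, Trf, Tnc, Sparc and the cell cycle regulators Cdkn2a, Ccnd1 and Ccnd2 fell. Of 11912 genes with a mean of at least 1 FPKM, 86 changed by limma at an adjusted p under 0.05, 39 of them higher and 47 lower in aged libraries. Of these calls, 10 were kept without limma's trend and 21 with the replicate number as a block. Twist1, Cdkn2a and Ccnd1 were kept in neither (limma adjusted p of Ccnd1 0.310 and 0.163). Ccnd1 and Ccnd2 were named only after their values were seen. Most changes were small, with a median absolute log2 change of 0.39 among the 86 genes, and 8 genes reached an absolute log2 change of 1. The values of young and aged libraries did not overlap in 17.6% of tested genes, against 10% by chance.

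The transcript with the largest log2 rise among the named genes was Col1a1 (gene 12842, mm10 chromosome 11, 94936224 to 94953042), a fibrillar collagen chain. Its mean was 0.423 ± 0.115 FPKM (SD, n = 3) in young and 2.46 ± 0.390 FPKM (SD, n = 3) in aged libraries, about 13.6 and 76.9 estimated reads. The log2 change was 1.28 ± 0.15 (SE), with a limma adjusted p of 0.0107. Of the other markers of fibroblasts and pericytes, Col1a2 lay at 0 to 0.04 FPKM in young and 0.54 to 0.75 FPKM in aged libraries, Col3a1 at 0 to 0.06 and 0.1 to 0.16 FPKM and Pdgfra at 1.48 to 1.59 and 1.96 to 2.62 FPKM. Pdgfra is also a member of the list of oligodendrocyte lineage markers. Dcn lay at 0 to 0.1 FPKM and Pdgfrb at 0 to 0.03 FPKM in all 6, while Myl9 and Tagln had means of 2.79 and 2.02 FPKM and ranges that overlapped between the ages. Vegfa (gene 22339, chromosome 17, 46016993 to 46032377) went from 22.2 ± 1.5 to 43.0 ± 2.59 FPKM (SD, n = 3 each), a log2 change of 0.92 ± 0.06 (SE) with a limma adjusted p of 0.00115. Slc16a3, a lactate exporter, rose from 1.92 to 5.84 FPKM, and the neuronal-type glucose transporter Slc2a3 from 5.92 to 9.85 FPKM. Ero1l, an oxidase of protein folding in the endoplasmic reticulum, rose from 9.85 to 15.4 FPKM. Bnip3, a mitophagy receptor, rose from 9.87 to 16.3 FPKM, and the stress-induced pseudokinase Trib3 from 2.52 to 5.33 FPKM. The glial receptor Gpr37l1 rose from 44.5 to 75.3 FPKM. The interferon-inducible Ifi27 rose from 17.3 to 29.6 FPKM and the phosphofructokinase Pfkl from 27.8 to 40.2 FPKM. Hist1h4i rose from 14.4 to 21.7 FPKM, which is uncertain because histone H4 genes are similar copies. Of the 19 replication-dependent histone genes listed, 14 had means under 1 FPKM, so these libraries hold few reads of most of them.

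By log2 change of FPKM + 1, the largest fall among the named genes was that of Igf2bp2 (gene 319765, chromosome 16, 22059009 to 22163299), which encodes a fetal-type RNA-binding protein. It went from 4.34 ± 0.116 FPKM (SD, n = 3) in young to 0.587 ± 0.222 FPKM (SD, n = 3) in aged libraries, about 91.5 against 12.1 estimated reads. The log2 change was -1.76 ± 0.14 (SE), with a limma adjusted p of 0.00196. The transcription factor Twist1 (gene 22160, chromosome 12, 33957671 to 33959831) went from 2.79 ± 0.416 to 0.337 ± 0.302 FPKM (SD, n = 3 each), about 24.5 against 2.9 estimated reads, with a limma adjusted p of 0.0114. Trf, which encodes transferrin (gene 22041, chromosome 9, 103208876 to 103230286), fell from 78.1 ± 1.37 to 48.5 ± 2.15 FPKM (SD, n = 3 each) with a log2 change of -0.68 ± 0.04 (SE) and a limma adjusted p of 0.000961. The imprinted gene Ndn fell from 48.9 to 26.3 FPKM, and the annexin Anxa3 from 33.9 to 18.2 FPKM. The homeobox genes Hlx and Barhl2 fell from 9.04 to 4.72 and from 6.81 to 3.12 FPKM. The sulfatase Sulf1 fell from 7.05 to 3.97 FPKM, and the adhesion molecule Chl1 from 8.34 to 4.94 FPKM. Rlbp1 fell from 14.7 to 9.0 FPKM, the potassium channel Kcnc4 from 11.6 to 7.14 FPKM and Pcp4l1 from 14.1 to 8.77 FPKM.

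**Figure D1:**
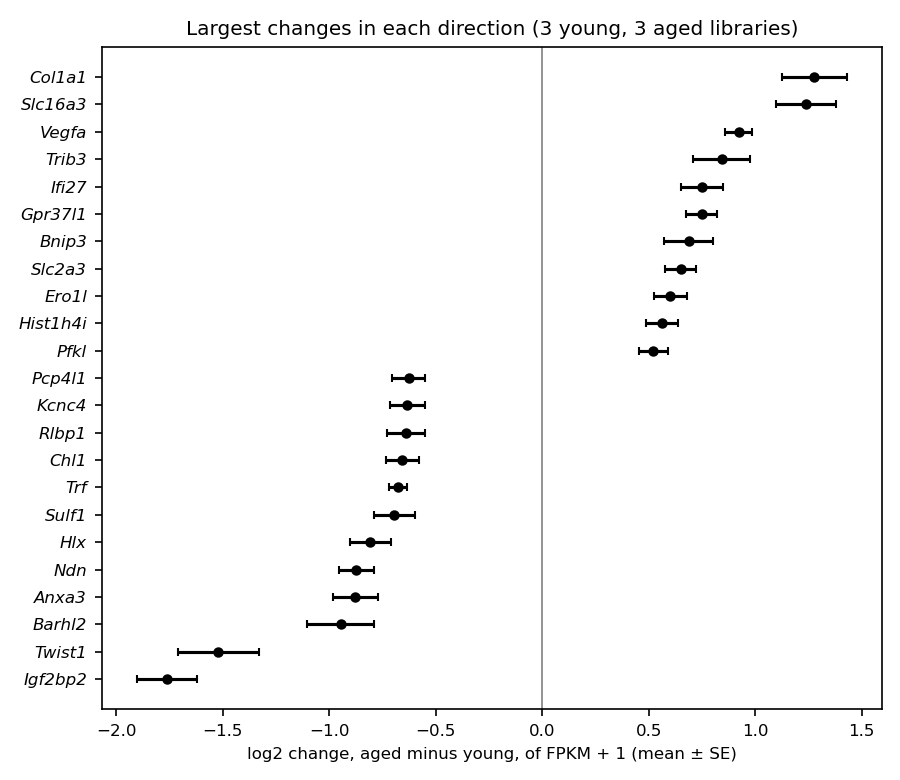
Log2 change of FPKM + 1 from young to aged libraries (x axis) for the 11 largest rises and 12 largest falls among the genes past the threshold whose groups did not overlap, without small RNA, clone-type and pseudogene symbols. Points lie at the limma estimate, with bars of 1 SE (3 libraries per group). The estimates run from -1.76 for Igf2bp2 to 1.28 for Col1a1.

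Most calls depended on the model and on all 6 libraries. Without limma's trend and with the replicate block, 6 of the 86 genes passed in both fits, among them Vegfa, Igf2bp2 and Trf, and 61 passed in neither. Mir3960 and Pisd-ps3, which the additional observations give as uncertain, also passed in both. Col1a1, Slc2a3 and Chl1 passed only without the trend (adjusted p with the block 0.0643, 0.0603 and 0.0643). Slc16a3, Gpr37l1, Ifi27, Pfkl, Ndn, Sparc, Tnc, Tpi1 and Ccnd2 passed only with the block (adjusted p without the trend up to 0.0953). The other called genes given in the results before the additional observations passed in neither. Among them were Twist1 (0.0566 without the trend and 0.0668 with the block), Cdkn2a (0.0809 and 0.0511), Pgk1 (0.128 and 0.0576) and Gpi1 (0.135 and 0.0608). Of the 86 genes, 25 passed in each of the 6 fits that left out 1 library and 13 passed in none. Vegfa, Col1a1, Slc16a3, Slc2a3, Gpr37l1, Igf2bp2, Trf, Ndn, Anxa3, Hlx, Chl1 and Pcp4l1 passed in all 6. Twist1 lost its call without young 1 or young 3 (highest adjusted p 0.0620), Ero1l without young 3 or aged 3 (0.0529), and Ifi27 without young 3 or aged 1 (0.0556). Pfkl lost it without young 3, aged 1 or aged 3 (0.0637) and Kcnc4 without young 1, young 2 or aged 3 (0.0660). Hist1h4i lost it without young 1, young 3, aged 1 or aged 3 (0.0681), Sulf1 without young 1, young 3, aged 2 or aged 3 (0.0799) and Bnip3 without young 2, aged 1, aged 2 or aged 3 (0.138). The call was kept only without young 1 for Rlbp1 (highest adjusted p 0.0841), only without aged 1 for Trib3 (0.125) and only without aged 3 for Barhl2 (0.159).

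Among the 23 gene lists tested, the list that moved most by its camera test was glycolysis. Of its 19 members, 10 rose and 0 fell by limma, 9 did not pass, and 14 rose and 0 fell when p was adjusted over the list alone. Pgk1 went from 417.9 ± 2.82 to 496.8 ± 7.09 FPKM (SD, n = 3 each; limma adjusted p = 0.00464), Tpi1 from 214.3 ± 5.22 to 269.8 ± 7.60 FPKM (0.00483) and Gpi1 from 329.4 ± 6.17 to 390.8 ± 3.42 FPKM (0.00687). Besides these, Slc16a3 and Pfkl, the called members were Ldha, Eno1, Gapdh, Pgam1 and the glucose transporter Slc2a1, named here after their values were seen, with means 1.13 to 1.46 times those of young libraries. Gapdh and several other members have processed pseudogenes, which the authors' counting could have split. The median log2 change of the list was 0.20, 18 of 19 members were higher in aged libraries, and the camera adjusted p was 3.39e-21 with a preset correlation of 0.01. With an estimated correlation the adjusted p was 0.132 (unadjusted p = 0.00574), and by fry, which asks whether the members move 1 way on balance, it was 0.00164. Without young 3, the adjusted p of Ldha was 0.0506. Eno1 lost its call without young 1, 2 or 3 (up to 0.0648) and Gapdh without young 1, young 3 or aged 1 (0.0691). Slc2a1 lost it without young 2, young 3, aged 2 or aged 3 (0.0854) and Pgam1 in all fits but the one without aged 2 (0.122).

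**Figure D2:**
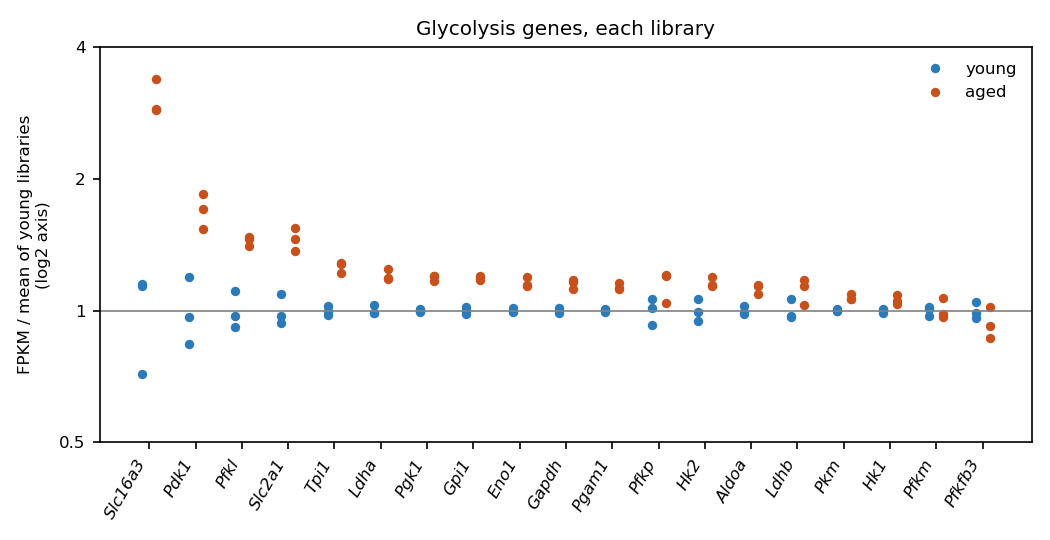
FPKM of each glycolysis gene in each of the 6 libraries, divided by the mean of the 3 young libraries (log2 axis; blue young, orange aged). Slc16a3 stands highest, at 3.05 times the young mean on average, and Pfkfb3 is the member whose aged mean lies below the young mean, at 0.935 times.

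The p53 target list fell, with 0 of its 19 members past limma over all genes tested (9 were lower and 2 higher at an unadjusted p under 0.05), and 2 fell when p was adjusted over the list alone. Eda2r was at 22.9 ± 1.14 FPKM in young and 19.3 ± 0.661 FPKM in aged libraries (SD, n = 3 each), Plk2 at 88.5 and 78.4 FPKM, Zmat3 at 23.3 and 20.7 FPKM and Ccng1 at 89.9 and 82.5 FPKM. The median log2 change was -0.12, with 16 of 19 members lower and a camera adjusted p of 0.000823. That adjusted p was 0.144 with an estimated correlation and 0.000829 by fry.

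Oligodendrocyte lineage markers rose as a list (median log2 change 0.13, 8 of 11 members higher, camera adjusted p = 0.00762), with 0 members past limma over all genes. The adjusted p was 0.199 with an estimated correlation, 0.00334 by fry, and 0.296 with no filter on low values (median 0.04). At an unadjusted p under 0.05, and also adjusted over the list alone, 5 were higher and 1 lower. The proteoglycan Cspg4 was at 13.9 ± 1.07 FPKM in young and 18.6 ± 1.17 FPKM in aged libraries (SD, n = 3 each), Gpr17 at 1.37 and 2.43 FPKM, Olig1 at 1396 and 1484 FPKM and Cnp at 69.1 and 75.8 FPKM. Of the members that were lower, Bcas1 was at 8.81 and 7.50 FPKM and Cldn11 at 5.47 and 4.26 FPKM.

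The lists of proliferation genes passed camera with small changes, and lost their calls in several settings. For 28 mitosis genes the median log2 change was 0.04 (25 higher, camera adjusted p = 0.0187). It was 0.05 for 30 DNA replication genes (24 higher, camera adjusted p = 0.0448). The calls were lost with an estimated correlation (adjusted p = 0.285 for mitosis and 0.252 for replication), by fry (0.0681 and 0.0992), after quantile normalization (0.0664 and 0.102), after rescaling to TPM (0.0577, with a median of 0.023, and 0.0986) and without limma's trend (0.0597 and 0.0817). That of replication was also lost among genes of at least 5 FPKM (0.0598) and with the replicate number as a block (0.0720). Both were also lost without young 1 (0.0594 and 0.0908), young 3 (0.107 and 0.236) or aged 1 (both 0.103), and the replication list without aged 3 (0.0976). Of both lists, 0 members passed limma over all genes or adjusted over the list alone (3 and 1 were higher at an unadjusted p under 0.05). Among mitosis genes, Ube2c was at 149.1 FPKM in young and 163.3 FPKM in aged libraries, Plk1 at 63.6 and 69.2 FPKM, Ttk at 14.4 and 16.04 FPKM and Foxm1 at 34.6 and 37.2 FPKM. Of the replication genes, Cdc45 was at 22.2 and 25.1 FPKM, Rfc4 at 26.5 and 29.8 FPKM, Lig1 at 58.7 and 62.9 FPKM and Gins4 at 27.6 and 30.5 FPKM.

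Extracellular matrix and adhesion genes moved in both directions, with 1 of 21 members higher and 2 lower by limma and 2 higher and 4 lower adjusted over the list alone. Sparc, a matricellular protein, fell from 99.6 ± 3.11 to 73.0 ± 2.66 FPKM and Tnc, the tenascin C of the stem cell niche, from 305.2 ± 2.5 to 245.9 ± 6.09 FPKM (SD, n = 3 each, both limma adjusted p = 0.00398). The proteoglycan Cspg5 rose from 93.8 to 106.9 FPKM (0.0406, and up to 0.166 with any 1 library left out), and Bcan was at 228.6 and 253.7 FPKM. The list median was -0.046 (-0.016 without aged 3 and -0.081 without aged 2), with a camera adjusted p of 0.0448. The adjusted p was 0.476 with an estimated correlation, 0.106 by fry, 0.0672 after quantile normalization, 0.0629 after rescaling to TPM, 0.0763 with the replicate number as a block and 0.0817 without limma's trend. It was 0.1002 with no filter and 0.135 after removal of GC and length trends, and over all alternatives it ranged from 0.00731 to 0.476. The call was kept only without aged 2 among the 6 fits with 1 library left out, and the highest adjusted p among the others was 0.221, without aged 3.

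**Figure D3:**
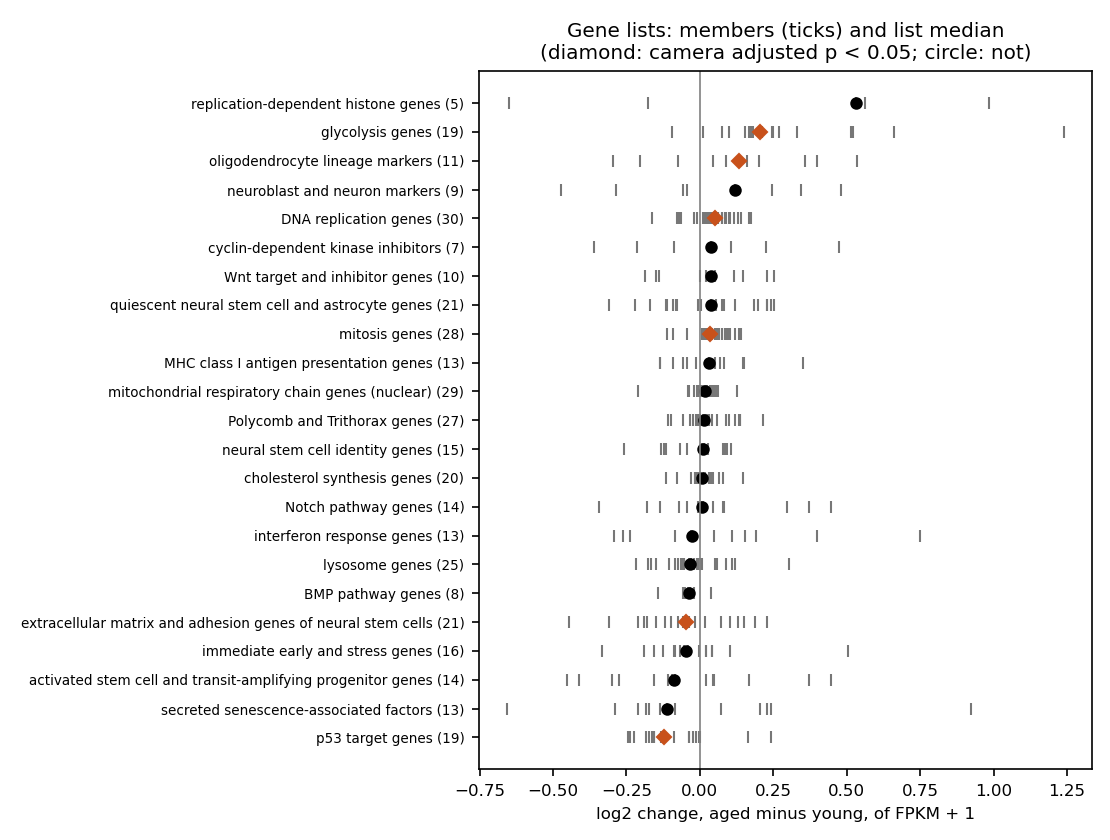
Log2 change of FPKM + 1 from young to aged libraries for the kept members (ticks) and the median (large symbols) of each of the 23 tested lists, with the number of members in brackets. Orange diamonds are the 6 lists with a camera adjusted p under 0.05, and black circles the 17 others.

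Most genes that mark stem cell identity and state did not pass the test. Sox2 was at 170.6 ± 4.89 FPKM in young and 181.7 ± 5.11 FPKM in aged libraries (SD, n = 3 each), Nes at 273.0 and 260.5 FPKM, and Egfr at 68.6 and 64.8 FPKM. Mki67 was at 62.3 and 63.7 FPKM, Gfap at 3.69 and 4.49 FPKM and Olig2 at 538.3 and 555.0 FPKM. The limma adjusted p of these 6 genes ran from 0.358 to 0.828. Dcx lay at 0.29 to 0.80 FPKM in the 6 libraries, under the filter. Cdkn1a, the p21 inhibitor, was at 248.7 and 233.9 FPKM and did not pass, whereas Cdkn2a (gene 12578, chromosome 4, 89274473 to 89294619) fell from 126.5 ± 0.419 to 98.4 ± 5.25 FPKM (SD, n = 3 each), a log2 change of -0.36 ± 0.04 (SE) with a limma adjusted p of 0.0102. A gene-level value cannot tell apart the transcripts of Cdkn2a that encode p16 and p19.

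The 17 other tested lists did not pass camera (adjusted p from 0.211 to 0.997), and 10 of them held called members. Camera looks for a shift in 1 direction, so it can miss lists whose members move both ways. With p adjusted over the list alone, 4 of 21 quiescence and astrocyte genes rose and 5 fell. Of 14 activated stem cell genes 3 rose and 3 fell, and of 13 secreted senescence factors 3 rose and 4 fell. Ccnd2, a cyclin of cycling progenitors, fell from 305.8 to 248.4 FPKM, and the Notch ligand Dll3 rose from 13.2 to 18.4 FPKM, in lists of activated stem cells and of the Notch pathway. Cpe fell from 564.2 to 501.1 FPKM among 21 quiescence and astrocyte genes, Ccnd1 from 654.6 to 594.0 FPKM among Wnt targets and Cd24a from 80.7 to 66.0 FPKM among neuroblast and neuron markers. H2-K1 rose from 23.3 to 30.0 FPKM among MHC class I genes, uncertain because its family is multicopy. The lists of cyclin-dependent kinase inhibitors, secreted senescence factors, interferon response and histones held Cdkn2a, Vegfa, Ifi27 and Hist1h4i. Ccnd2, Dll3, Cpe, Ccnd1, Cd24a and H2-K1 were named after their values were seen. Ccnd2 passed with any 1 library left out, Cd24a lost its call without young 1 or young 2 (up to 0.0630), and Cpe, Ccnd1, Dll3 and H2-K1 lost it in at least 4 of the 6 fits. No member was called among neural stem cell identity, lysosome, BMP pathway, Polycomb and Trithorax, respiratory chain, cholesterol synthesis and immediate early genes (0 of 140 by limma, 19 at an unadjusted p under 0.05, camera adjusted p from 0.251 to 0.545 across these 7 lists). The median and the camera direction had opposite signs for stem cell identity genes (median 0.01), kinase inhibitors (0.04) and interferon genes (-0.03), and camera and fry differed in direction for senescence factors and for neuroblast and neuron markers.

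Few markers of other cell types of the region exceeded 1 FPKM. Microglial genes reached a mean of 2.70 FPKM (Cd68) and endothelial genes 2.04 FPKM (Egfl7, with means of 1.51 FPKM in young and 2.56 FPKM in aged libraries, no overlap and a limma adjusted p of 0.147), with Pecam1 and Ptprc at 0.17 FPKM or less in every library. Among ependymal and choroid plexus markers, Foxj1 lay at 8.49 to 12.7 FPKM over the 6 libraries and Enpp2 at 9.85 to 12.65 FPKM in young and 13.98 to 15.73 FPKM in aged ones (limma adjusted p = 0.1815). Hydin and Kcnj13 stayed at 0.14 FPKM or less. Xist was at 67.4 ± 0.804 FPKM in young and 66.9 ± 4.08 FPKM in aged libraries (SD, n = 3 each), and Ddx3y and Uty at 0.04 FPKM or less in each library.

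The libraries were alike. Pearson correlations of log2 values across genes, which are not independent replicates, ran from 0.988 to 0.990 within groups and from 0.986 to 0.988 between them. The first principal component, 25.6% of the variance, separated young from aged. It was only a little larger than the next components, which held 22.1%, 19.5%, 17.5% and 15.3%. Nothing in the labels says that the 3 libraries of a group came from separate cultures, so the p-values measure the spread between these libraries, which may be technical.

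**Figure D4:**
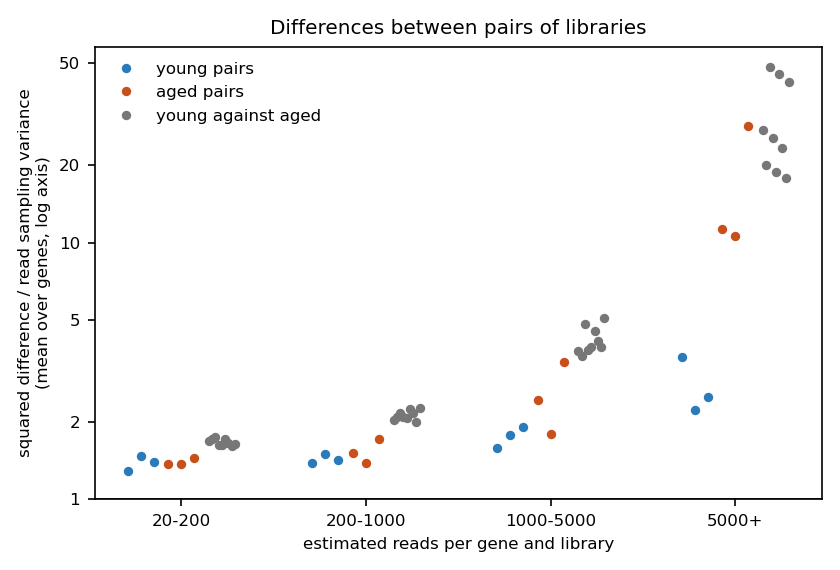
Mean squared difference between 2 libraries divided by the variance expected from read sampling (log axis), for genes grouped by estimated reads, with a point for each pair of libraries (blue young pairs, orange aged pairs, grey young against aged). At 1000 to 5000 reads the young pairs lie at 1.58 to 1.91, the aged pairs at 1.79 to 3.41 and the pairs of young against aged at 3.62 to 5.06.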

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

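All alternatives here were planned, except the filter on estimated reads and the GC and length correction, which were chosen after seeing the data. Without limma's trend 11 genes changed (7 higher, 4 lower), against 86 (39 and 47). Leaving out small and unnamed RNA symbols gave 131 genes (65 higher), and a mean of at least 20 estimated reads gave 60 higher genes among 123. With no filter 29 genes were lower. An absolute log2 change of at least 1 left 8 genes and an adjusted p under 0.01 left 19. With 1 library left out, 39 (without young 3) to 70 (without aged 2) genes changed, 47, 45, 48 and 57 of them without young 1, young 2, aged 1 and aged 3, with 17 to 37 higher and 22 to 33 lower. These fits have fewer samples, and for the other changes the cause was not tested. The other settings gave 84 to 109 genes, except for no filter, with 59, and the replicate block, with 22 (11 higher, 11 lower). Of the 86 calls, 10 were kept without the trend and 21 with the block. Of the 6 lists, 3 passed after quantile normalization, after rescaling to TPM, without limma's trend and by fry, and 3 to 6 with 1 library left out. With camera's estimated correlation 0 passed, 4 had an unadjusted p under 0.05, and fry passed 3. Outside the 6, respiratory chain genes passed without aged 2 (adjusted p = 0.00278) and histone genes without aged 3 (0.0184). The replicate numbers did not pair the libraries: same-numbered deviations correlated at 0.008, -0.072 and 0.108, and not every library correlated best with its own number. No called list and no called gene among those named changed direction, but the medians of several lists that did not pass changed sign under some settings, and fry and camera differed in direction for senescence factors and for neuroblast and neuron markers. The lower genes outnumbered the higher ones in the main fit and not in every alternative. Count-based alternatives were not run. Depth limits genes of few reads: 4 of the 86 changed genes had a mean under 20 estimated reads.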

Other observations

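The tests of GC content, scaling, repeat draws, read number and other splits in this part were chosen only after the results they bear on were seen. The 3 gene lists of hypotheses were also drawn up after the changed genes were known, and without them, but before their members were tested, apart from Cdkn1c and Sesn2, whose values had been seen in other lists. The bootstrap intervals of their medians resample genes, so they do not measure the spread between libraries.

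Several further changed genes were singled out after their values were seen. Hbegf fell from 38.7 to 30.2 FPKM, Kitl from 19.6 to 14.8 FPKM and Angpt2 from 25.5 to 16.9 FPKM (limma adjusted p = 0.0118, 0.0211 and 0.0216). The galectin Lgals1 fell from 474.2 to 377.1 FPKM (0.00714), the chromatin protein Hmga1 from 79.6 to 58.7 FPKM (0.00687) and Trp53i11 from 201.0 to 154.0 FPKM (0.00149). These last 3 passed with any 1 library left out and with the replicate number as a block, but not without limma's trend (adjusted p up to 0.0990). Hbegf, Kitl and Angpt2 passed neither with the block nor without the trend. Hbegf also lost its call without young 1, young 2 or aged 1 (up to 0.0630), Angpt2 without young 2, young 3, aged 2 or aged 3 (0.0963), and Kitl in all fits but the one without aged 2 (0.108). Pisd-ps3, a pseudogene that shares sequence with its parent gene, went from 13.3 to 25.8 FPKM and is uncertain for that reason.

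The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 86 genes and the highest other split 1. For each direction (39 and 47 genes) the highest other was 1, and for lists (6) it was 2. In each case 1 of the 10 splits, the real one, gave a result as large.

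Glycolysis genes were higher in aged libraries. GC content or transcript length does not account for it as a whole: with those trends removed the list median was 0.186 against 0.203, and the list passed camera with the preset correlation. With an estimated correlation it did not pass in the main fit (adjusted p = 0.132). Scaling by the authors does not either, since the lowest median over 3 other scalings was 0.18. A candidate explanation is a wider hypoxia-type response: 21 hypoxia-responsive genes outside glycolysis had a median log2 change of 0.165 (95% bootstrap interval 0.066 to 0.241), 16 were higher and 5 lower, and camera gave an adjusted p of 6.3e-06 over 3 lists (0.0196 with an estimated correlation). Of these genes, 0 passed limma over all genes tested, and 8 were higher when p was adjusted over the list alone. Donor age, and oxygen, density or passage in culture, stay open, because the design does not separate them.

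Differences between libraries of a group were set against read sampling. The squared difference over sampling variance was 1.58 to 1.91 in young and 1.79 to 3.41 in aged pairs at 1000 to 5000 estimated reads. At over 5000 reads it was 2.22 to 3.58 in young and 10.59 to 28.58 in aged pairs. If the libraries of a group were repeat draws from 1 library, that ratio should not grow with depth. It was higher at 1000 to 5000 than at 20 to 200 estimated reads, with separate intervals, in 3 of 3 aged pairs, which argues against repeat draws for that group. In young libraries it was in 2 of 3 pairs, both with young 2. The test asked for growth in every pair, so for the young group as a whole it does not decide. Read pair by pair, the growth argues against young 2 being a repeat draw of young 1 or young 3. For young 1 against young 3 the intervals overlapped (1.37 to 1.58 and 1.57 to 2.05). At 1000 to 5000 reads the ratio of that pair, 1.78, was still above the 1.58 of young 1 against young 2. Repeat draws cannot be told apart from separate libraries for that pair. At over 5000 reads the median coefficient of variation was 1.11% in young and 2.25% in aged libraries, over 82 genes, against 1.14% and 1.16% from read sampling. A median of coefficients from 3 libraries tends to lie below the true spread. The young value therefore does not show that these libraries differ by read sampling only, and their pairs gave 2.22 to 3.58 for the same genes. Whether a group's libraries share a culture stays open, and with it whether the changes may be those of a culture instead of an age.

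The microRNA precursors Mir3960, Mir1902 and Mir207 had the largest fitted changes, but few reads may be the source. The highest mean was 5.5 estimated reads per library, for Mir207 in young libraries (12.9 FPKM, against 1.23 FPKM in aged). Mir3960 and Mir1902 were listed at 0 in all young libraries and had means of 9.91 and 6.41 FPKM in aged ones, from 3.8 and 2.7 estimated reads. Mir3960 nevertheless passed with any 1 library left out, without limma's trend (adjusted p = 0.0414) and with the replicate block (0.0209). A biological explanation was not tested.

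Trib3 may belong to an integrated stress response. The 20 other genes of that response had a median log2 change of 0.096 (95% bootstrap interval 0.057 to 0.125), 17 were higher, and camera gave an adjusted p of 1.05e-05 over 3 lists. With an estimated correlation the call was lost (adjusted p = 0.0529). Of the 20 genes, 0 passed limma over all genes tested or adjusted over the list alone. For the imprinted genes Ndn and Peg10, a wider fall was not settled: 13 other imprinted genes had a median of -0.058 (interval -0.117 to 0.015, camera adjusted p = 0.0606), with 9 lower. By fry the unadjusted p was 0.00708. Of the 13 members, 0 passed limma over all genes tested, and 3 were lower when p was adjusted over the list alone. Peg10 itself lost its call in all 6 fits that left out 1 library (up to 0.165). Igf2r was at 7.09 and 5.87 FPKM and Grb10 at 1.67 and 0.583 FPKM (limma adjusted p = 0.229 and 0.0743). Of the 4 members that were higher, Cdkn1c was at 1.73 and 2.77 FPKM and Snrpn at 32.4 and 36.9 FPKM (0.339 and 0.314).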
